A study of Mus musculus with 9 samples.

How the data were processed

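RNA from ventricles of 9 mice was hybridised to 9 one-colour oligonucleotide arrays, 1 array per animal. The deposited table holds 1 intensity value per probe set and array for 12488 probe sets. Per the labels, the arrays were scanned at a photomultiplier setting of 10%. How the authors computed the intensity values is not given in the sources used here. The deposited values lie on a linear scale and are above 0, and the mean without the lowest and highest 2% of probe sets is 500.4 on every array, so each array had been scaled to a common level before deposition. Gene symbols were taken from the annotation table supplied for the array platform. That table gives 1 symbol to 10855 probe sets and several symbols to 396, and it does not list 1237 others. The Entrez gene of 10839 annotated probe sets was found in a mouse reference gene table (assembly GRCm38.p6), and the symbol was the same there for all of them. The array files name no genome build, so no coordinates are printed.

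The 3 groups were read from the sample titles. They are caPI3K, dnPI3K and NTG, with 3 arrays each, and no sample was left out. Replicate numbers follow the order of deposition and pair no animals. The deposited values of the 9 arrays were quantile normalized to each other, raised to a floor at the 20th percentile (35.34) and converted to log2. A probe set was tested if it lay above the floor on at least 3 of the 9 arrays, and the 66 array control probe sets were left out after normalization. This left 10645 probe sets, of which 9420 carry 1 symbol and represent 7484 genes. Means and standard deviations (SD) of named genes are of normalized intensities before the floor and the logarithm. Where a group lies on the floor, a fold change depends on the floor chosen.

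Group differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend). All 9 arrays entered 1 fit with group as its only term, which left 6 residual degrees of freedom before moderation. The comparisons were caPI3K against NTG, dnPI3K against NTG and caPI3K against dnPI3K. The moderated F tested for any difference between the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, two-sided, with a threshold of 0.05. Standard errors (SE) are the moderated ones. The 3 NTG arrays serve both transgenic groups, so the correlation of both effects across probe sets was set beside 100 simulated draws in which both groups were unchanged but shared their controls.

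Before the data were examined, 33 gene lists for pathways, complexes and cell types of the heart were fixed, of which 32 had at least 5 measured genes and were tested. Each gene entered with the probe set that had the highest mean over the 9 arrays. Lists were tested with camera, which compares a list with all other genes, at its preset correlation of 0.01 and, as an alternative, at a correlation estimated from the residuals. Adjustment was over the lists of a comparison. Named genes were chosen by a rule fixed at the same time. A gene with several probe sets is represented by the one with the highest mean over the 9 arrays. For each comparison the rule takes up to 10 genes per direction with the largest change among those past the threshold whose 3 arrays of either group all lay beyond those of the other. It also takes every measured gene for a class I PI3K subunit, the markers Nppa, Nppb, Acta1, Myh6, Myh7 and Atp2a2, and up to 4 members of each list with the smallest p. Other probe sets of a named gene are mentioned where they gave another result, and a gene singled out beyond the rule is said to be so.

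Alternative settings changed 1 choice at a time. They were the deposited values without quantile normalization, scaling of each array to the same median, a floor at the 5th or 40th percentile, no filter on dim probe sets, only probe sets above the median, no intensity trend, robust moderation, array weights, 1 probe set per gene, a fit of only the 2 groups compared, the animal number series as a block, and each of the 9 arrays left out in turn. A pair of settings that deal with Myl4 and Myl7 was added after seeing the data.

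The procedure was tested on simulated data with changes added to normal noise, drawn independently for each probe set with its moderated SD from these arrays. At a 2-fold change, 46.2% of changed probe sets were recovered for caPI3K against NTG, 32.3% for dnPI3K against NTG and 48.5% for caPI3K against dnPI3K. At a 4-fold change the shares were 84.6%, 70.3% and 84.6%. Noise, array numbers and sizes of change were set alike for the 3 comparisons. Differences between these shares therefore come from the random draws and do not rank the comparisons. The simulations made 3, 2 and 5 false calls among 10476, 10474 and 10469 probe sets. In the simulation for caPI3K against NTG, camera called 0 of 32 unchanged lists, and a list of 20 genes moved by 0.50 on the log2 scale had an adjusted p of 1.17e-14. The simulated genes were independent, whereas the estimated correlation was 0.308 for fatty acid oxidation and 0.527 for interferon response genes. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Other splits of the real arrays gave up to 5 lists in caPI3K against NTG, 4 in dnPI3K against NTG and 2 in caPI3K against dnPI3K. Arrays give no counts, and the number of arrays limits the precision. The median SE of a log2 fold change was 0.251. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.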

Results

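Gene expression was measured in the ventricles of 9 mice on 1-colour oligonucleotide arrays, with 1 array per animal and 3 animals per group. Mice of the caPI3K group carried a transgene for a constitutively active phosphoinositide 3-kinase (PI3K), mice of the dnPI3K group a dominant negative form of the enzyme, and NTG mice no transgene. PI3K makes the membrane lipid that recruits the kinase Akt and acts below the receptors for insulin and insulin-like growth factor. The labels state that hearts exceeded those of wild type littermates by 20% in caPI3K mice and fell short of them by 17% in dnPI3K mice. The animal numbers in the sample titles interleave between the caPI3K and NTG groups, and those of the dnPI3K group form a separate, lower series.

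Every array had the same 2% trimmed mean (500.4), and array medians lay between 174.8 and 194 intensity units. Correlations between arrays across all probe sets tested were 0.947 to 0.966 within groups and 0.939 to 0.959 between groups. NTG arrays correlated no more with each other (mean 0.9504) than with the other groups (0.9506). On the second component, with 13.8% of the variance, NTG replicate 2 scored 38.99 and the other arrays -17 to 6.41. The first principal component held 22.2% of the variance. The dnPI3K arrays scored 26.4 to 28.9 on it, and the other arrays scored -22.9 to -1.33. The dnPI3K arrays also stood apart in array control probe sets that do not measure the heart's messenger RNA. The geometric mean of the bacterial and phage spike-in controls was 1760 ± 210 (SD, n = 3) on dnPI3K arrays, 3035 ± 458 on NTG arrays and 3089 ± 303 on caPI3K arrays. The 3′ control probe set for 18S ribosomal RNA read 6059 ± 2480 in dnPI3K, 542.3 ± 112 in NTG and 518.3 ± 37.1 in caPI3K. The ratio of 3′ to 5′ signal of Gapdh, a measure of RNA integrity, was 0.813 ± 0.0314 in dnPI3K, 0.849 ± 0.0147 in NTG and 0.839 ± 0.0320 in caPI3K. The same ratio of Actb was 1.29 ± 0.0105 in dnPI3K, 1.22 ± 0.0767 in NTG and 1.13 ± 0.0867 in caPI3K.

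**Figure D1:**
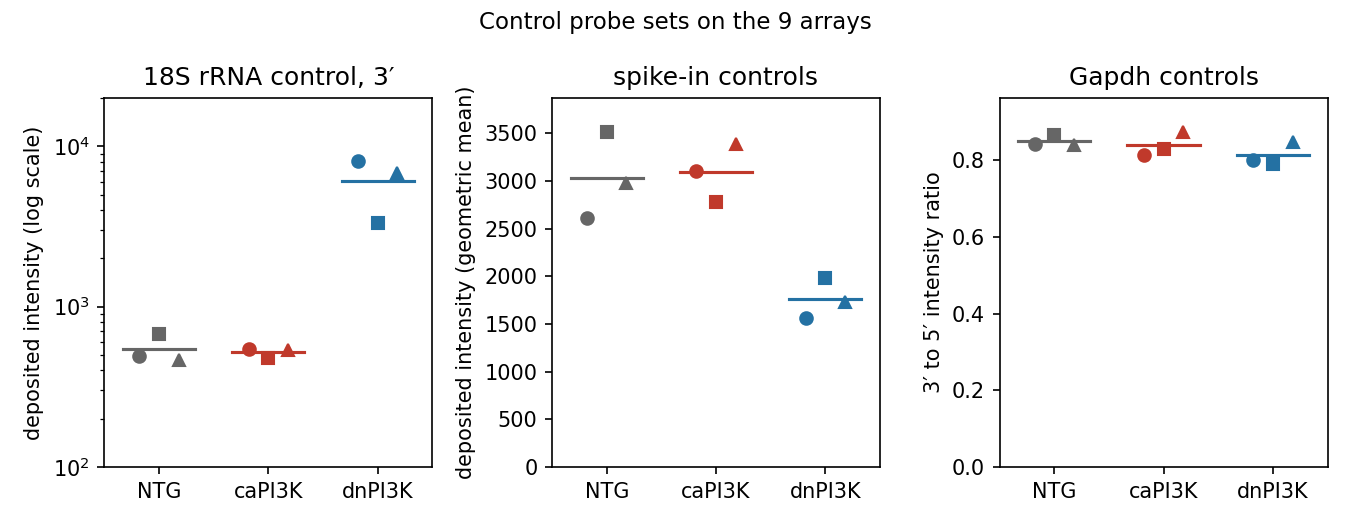
Deposited intensity of the 3′ control probe set for 18S ribosomal RNA (log axis), geometric mean intensity of the spike-in controls, and 3′ to 5′ intensity ratio of the Gapdh controls on the 9 arrays, with circles, squares and triangles for replicates 1, 2 and 3 and a line at each group mean. The 3 dnPI3K arrays lie at 3303 or above in the first panel and at 1984 or below in the second, apart from the other arrays, and within 0.789 to 0.848 in the last.

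The comparison of caPI3K with NTG asks which transcripts differed in the larger hearts. Skeletal alpha-actin (Acta1), an actin of the fetal heart that returns in hypertrophy, rose 2.28-fold, from 8670 ± 1120 in NTG to 19780 ± 2210 in caPI3K (mean normalized intensity ± SD, n = 3 each). Beta-myosin heavy chain (Myh7), the slow myosin of the fetal mouse ventricle, rose 2.04-fold, from 11210 ± 84.9 to 23220 ± 4930. Hsph1, a large chaperone of the heat shock response, rose 1.88-fold, and Tfpi, an inhibitor of the tissue factor pathway of coagulation, fell from 990.2 ± 204 to 460.2 ± 36.5. The natriuretic peptide genes Nppa and Nppb did not pass the test, with log2 fold changes of -0.73 ± 0.461 (SE) and -0.09 ± 0.146, and neither did adult alpha-myosin heavy chain (Myh6, -0.12 ± 0.0827) or the calcium pump gene Atp2a2 (-0.13 ± 0.107). Myh6 ranked 1 to 10 in brightness on every array, where quantile normalization holds values close together. Its SE therefore overstates the precision, and over all alternatives its change lay at -0.231 to -0.0272.

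In all, 9 of 10645 probe sets passed the threshold, 5 higher and 4 lower in caPI3K, and 734 had an unadjusted p under 0.05. With no change at all, a share of 0.05 of the 10645 would be expected under it. The log2 fold changes were 1.19 ± 0.155 for Acta1, 1.03 ± 0.134 for Myh7, 0.91 ± 0.119 for Hsph1 and -1.09 ± 0.146 for Tfpi, each with an adjusted p of 0.0255. A second Myh7 probe set changed by 0.66 ± 0.436 and did not pass (adjusted p = 0.814). Both Myh7 probe sets are of a type that shares sequence within a gene family. The other named genes were Tpbpa (log2 fold change 1.97 ± 0.289, adjusted p = 0.0386), Eepd1 (1.81 ± 0.250, adjusted p = 0.0286, with 2 of 3 NTG arrays on the floor) and the cornified envelope genes Sprr2k (-1.93 ± 0.274, adjusted p = 0.0327) and Sprr2g (-1.71 ± 0.226, adjusted p = 0.0255), whose probe sets share sequence with their gene family. With the floor at the 40th percentile Tpbpa changed by 1.05, and Eepd1 (0.26) did not pass. The remaining probe set has no gene name in the files and changed in opposite directions, -1.91 ± 0.211 in caPI3K (adjusted p = 0.0251) and 1.08 ± 0.211 in dnPI3K (adjusted p = 0.0304). None of the 4 measured PI3K subunit genes passed. Their log2 fold changes were 0.53 for Pik3r2, -0.29 for Pik3ca, -1.04 for Pik3cd (second probe set 0.14) and -0.21 for Pik3r1.

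**Figure D2:**
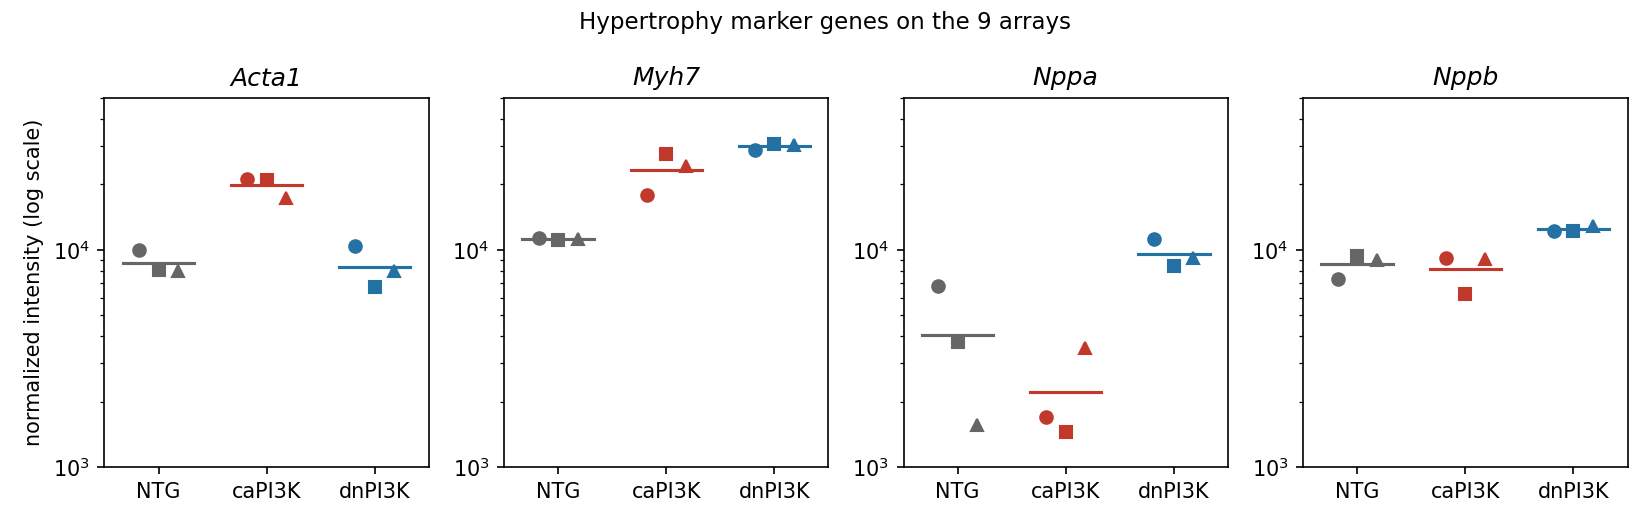
Normalized intensity (log axis) of Acta1, Myh7, Nppa and Nppb on the 9 arrays, with circles, squares and triangles for replicates 1, 2 and 3 and a line at each group mean. Acta1 is higher on the 3 caPI3K arrays, with a mean of 19780, than on the other 6, and Myh7 is higher on all 6 transgenic arrays than on the NTG arrays, which average 11210.

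The 9 calls depended on which arrays were included. Without NTG replicate 1 the count was 20. It was 7 without dnPI3K replicate 1, 2 without caPI3K replicate 1, caPI3K replicate 3 or dnPI3K replicate 2, and 0 without caPI3K replicate 2, dnPI3K replicate 3, NTG replicate 2 or NTG replicate 3. It was also 0 when limma was fitted to the 2 groups alone or with the animal number series as a block, and over the settings with 0 calls between 565 and 837 probe sets had an unadjusted p under 0.05. The lowest of these, 565 of 10540 without caPI3K replicate 2, is close to the share of 0.05 expected with no change. With 1 array left out the log2 fold change lay between 1.13 and 1.30 for Acta1, 0.88 and 1.20 for Myh7, 0.83 and 0.97 for Hsph1 and -1.19 and -0.93 for Tfpi. In animals numbered from 2800 (2 arrays per group) and from 3100 (1 per group), the log2 fold changes were 1.23 and 1.11 for Acta1, 0.98 and 1.12 for Myh7, 1.02 and 0.68 for Hsph1, -0.99 and -1.29 for Tfpi, -2.04 and -1.06 for Sprr2g, -1.82 and -2.16 for Sprr2k, 1.84 and 2.24 for Tpbpa and 1.87 and 1.69 for Eepd1. Nppa, which did not pass, was at -1.69 in the former and 1.18 in the latter. Scaling each array to the same median gave 9 higher and 4 lower.

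By gene list, 5 lists passed in this comparison, and none did with an estimated correlation. Of 42 measured proteasome genes 32 had a log2 fold change above 0, with a mean of 0.16 (camera adjusted p = 0.00459, and adjusted p = 0.255 with an estimated correlation), although 0 passed alone, over all genes or adjusted over the list alone. Examples were the proteasome activator Psme4 (0.41 ± 0.0998) and the 19S subunit Psmd6 (0.35 ± 0.0973). Of 24 heat shock and chaperone genes 17 were above 0 (mean 0.20, adjusted p = 0.00805, and adjusted p = 0.255 with an estimated correlation). Hsph1 was the gene that passed, and 2 passed adjusted over the list alone. Hspa1a (1.04 ± 0.283) and Hspa8 (0.33 ± 0.104) did not pass over all genes. Of 69 oxidative phosphorylation genes 55 were below 0 (mean -0.10, adjusted p = 0.00805, and adjusted p = 0.255 with an estimated correlation), among them Sdha (-0.37 ± 0.102). Of 22 citric acid cycle genes 17 were below 0 (mean -0.10, adjusted p = 0.0306, and adjusted p = 0.397 with an estimated correlation), among them Idh2 (-0.41 ± 0.128) and Mdh1 (-0.51 ± 0.190). Of 10 vascular smooth muscle marker genes 7 were below 0 (mean -0.24, adjusted p = 0.0306, and adjusted p = 0.255 with an estimated correlation), with Acta2, smooth muscle alpha-actin, at -0.56 ± 0.175. In the last 3 lists 0 genes passed either way. Of 21 fetal and hypertrophy marker genes 2 rose (Acta1 and Myh7), 4 rose and 1 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.312).

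With the deposited values, the oxidative phosphorylation, citric acid cycle and smooth muscle lists did not pass. Without NTG replicate 2, 1 of the 5 lists passed, and 2 did without NTG replicate 3. Without caPI3K replicate 1 or 2 the number was 3, and without NTG replicate 1 the heat shock list did not pass (adjusted p = 0.12, within a range of 0.000639 to 0.339 over its alternatives). With the 3 arrays of highest Myl4 and Myl7 left out, a setting chosen after seeing the data that kept 1 NTG array, none of the 5 passed. Over all alternatives the list means lay at -0.12 to -0.09 for oxidative phosphorylation, -0.20 to -0.09 for the citric acid cycle, 0.11 to 0.19 for the proteasome, 0.12 to 0.27 for heat shock and -0.36 to -0.20 for smooth muscle.

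The comparison of dnPI3K with NTG asks the same of the smaller hearts. Pik3r1, which encodes the p85 alpha regulatory subunit of PI3K, fell from 706.3 ± 145 in NTG to 148.3 ± 22.3 in dnPI3K (log2 fold change -2.24 ± 0.216, adjusted p = 0.000574). Ppara, the nuclear receptor that controls fatty acid oxidation genes, fell from 1729 ± 125 to 500.5 ± 142. Myh7 rose to 30010 ± 1030 (2.67-fold), beta-tropomyosin (Tpm2) rose from 409.5 ± 111 to 1264 ± 82.3, and the matrix-associated growth factor Ccn2 rose from 1659 ± 257 to 4336 ± 910. The fast skeletal light chain Myl1 fell from 4942 ± 1920 to 1164 ± 171 and the fast skeletal calsequestrin Casq1 from 2751 ± 522 to 771.6 ± 182. The dnPI3K arrays differed from the NTG arrays in spike-in and ribosomal RNA controls as well, and no NTG animal has a number near theirs.

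Past the threshold were 232 probe sets, 108 higher and 124 lower in dnPI3K, and 1577 had an unadjusted p under 0.05. Scaling to the same median gave 135 higher and 93 lower. Among genes represented by their brightest probe set, the largest falls were those of the atrial myosin light chains Myl4 (-5.48 ± 1.15, adjusted p = 0.04) and Myl7 (-5.19 ± 1.16, adjusted p = 0.0476), whose levels also differed within groups. Myl4 read 222.7 to 6896 on NTG arrays, 421.4 to 4304 on caPI3K arrays and 27.9 to 49.7 on dnPI3K arrays. A second Myl4 probe set fell by 1.73 (adjusted p = 0.0144). Of 13 atrial marker genes 10 were below 0 and 3 fell (mean -0.87), 1 rose and 4 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.178). Others were Akap9, an anchor of protein kinase A (-3.07 ± 0.281), Gdap10 (-2.81 ± 0.137, adjusted p = 6.43e-06) and the urocortin receptor Crhr2 (-2.67 ± 0.487), for which a second probe set changed by 0.19. Tyms-ps fell by 1.85 with a second probe set at 0.17. Wnk1, chosen after its values were seen, changed by -2.40 and -2.19 on a pair of probe sets that passed and by -0.07 on its brightest. The largest rises were those of Tbc1d10a (3.40 ± 0.609, second probe set 0.95), Bex1 (2.51 ± 0.309), Sgip1 (2.48 ± 0.502), Trabd (2.42 ± 0.388), the phosphatase Dusp8 (2.30 ± 0.302, second probe set 1.28), Tgfb1 (2.12 ± 0.433), Rhox5 (1.99 ± 0.345), Aff1 (1.93 ± 0.280), Lsm2 (1.88 ± 0.277) and Sema3b (1.86 ± 0.308, second probe set 0.74). NTG arrays lay on the floor for Aff1 (2 of 3) and for Bex1, Sgip1, Trabd, Tgfb1 and Sema3b (1 of 3 each), and dnPI3K arrays for Crhr2 (3 of 3), Akap9 (2 of 3) and Myl4 (1 of 3), so that the sizes of these changes depend on the floor. With the floor at the 40th percentile Tgfb1 (0.72), Aff1 (0.32), Sema3b (0.35), Crhr2 (-0.996), Myl4 (-3.98) and Myl7 (-4.18) did not pass, and with the floor at the 5th Aff1 (2.55) and Myl7 (-5.19) did not. With the floor at the 40th percentile Bex1 (1.19), Trabd (1.02), Rhox5 (0.92), Dusp8 (1.49), Lsm2 (1.25) and Akap9 (-1.59) passed with smaller changes.

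**Figure D3:**
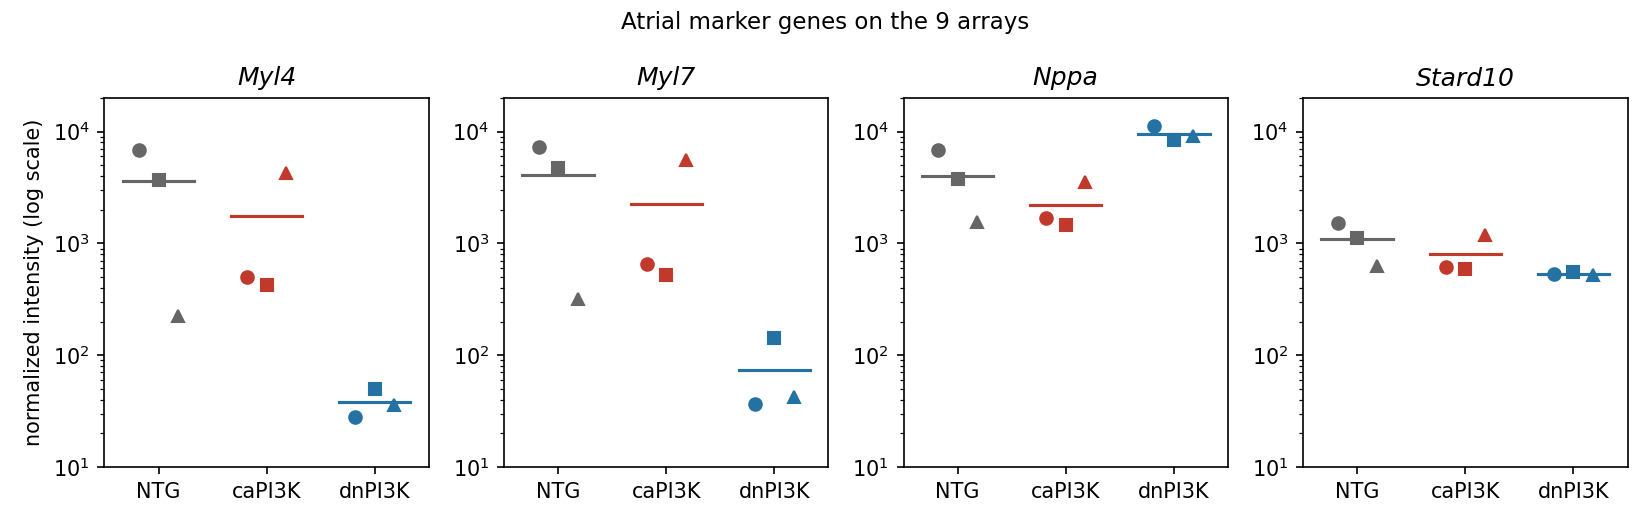
Normalized intensity (log axis) of Myl4, Myl7, Nppa and Stard10 on the 9 arrays, with circles, squares and triangles for replicates 1, 2 and 3 and a line at each group mean. Myl4 and Myl7 spread widely over the caPI3K and NTG arrays and are lowest in dnPI3K, with means of 37.9 and 73.7, while Nppa is highest in dnPI3K.

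Within the PI3K-Akt-mTOR list of 22 genes, Pik3r1 fell, and Akt2 (0.57 ± 0.117, adjusted p = 0.0352) and the insulin receptor substrate Irs2 (1.58 ± 0.331, adjusted p = 0.04) rose. Adjusted over the list alone 5 rose and 2 fell, and the list as a whole did not pass (adjusted p = 0.364). Pik3r2 (0.04), Pik3ca (0.34) and Pik3cd (0.15) did not pass. Of 25 fatty acid oxidation genes 20 were below 0 (mean -0.24, adjusted p = 0.00234, and adjusted p = 0.644 with an estimated correlation). Ppara and the fatty acid binding protein Fabp3 (-0.50 ± 0.0893, adjusted p = 0.0194) fell, and 8 fell adjusted over the list alone. The carnitine carrier Slc25a20 (-0.50 ± 0.118) and the dehydrogenase Acadm (-0.43 ± 0.114) did not pass over all genes. Of 21 fetal and hypertrophy marker genes, Myh7 (log2 fold change 1.42 ± 0.134), Tpm2 (1.66 ± 0.212, second probe set -0.65), Ccn2 (1.38 ± 0.198) and Acta2 (from 1272 ± 161 to 2555 ± 468) rose and Myl4 fell. Adjusted over the list alone 8 rose and 1 fell, and the list passed as higher (mean 0.16, adjusted p = 0.00921, and adjusted p = 0.474 with an estimated correlation). The second Myh7 probe set also rose (adjusted p = 0.0443). Acta2 is on the vascular smooth muscle list as well, where 8 of 10 genes were above 0 (mean 0.176, camera adjusted p = 0.361). Acta1 (-0.07 ± 0.155), Myh6 (-0.06 ± 0.0827) and Atp2a2 (-0.12 ± 0.107) did not pass. Over all alternatives Myh6 lay at -0.454 to -0.0132 and Atp2a2 at -0.362 to -0.0402. The small change and SE of Myh6 partly reflect quantile normalization, which holds the brightest probe sets close together.

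The natriuretic peptides fell short of the threshold. Their dnPI3K arrays all lay above the NTG arrays, but with 3 arrays per group 10% of unchanged probe sets separate by chance in either direction. Nppa read 9612 ± 1450 against 4046 ± 2660 (log2 fold change 1.48 ± 0.461, adjusted p = 0.148), and Nppb read 12430 ± 410 against 8561 ± 1090 (0.55 ± 0.146, adjusted p = 0.0949). Without NTG replicate 1 Nppa changed by 1.98 with an adjusted p of 0.0478, and without caPI3K replicate 2 the adjusted p of Nppb was 0.0321. Over all alternatives the adjusted p ranged from 0.000103 to 0.286 for Nppa and from 0.0321 to 0.401 for Nppb. The lowest for Nppa came from the settings for Myl4 and Myl7 (up to 2.61), which were chosen after seeing the data and rest on genes that Nppa itself followed within groups.

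Of 14 skeletal muscle marker genes 11 were below 0 (mean -0.55, adjusted p = 0.00234, and adjusted p = 0.218 with an estimated correlation). Myl1 (-2.02 ± 0.249) and Casq1 (-1.84 ± 0.219) fell, 3 fell adjusted over the list alone, and muscle creatine kinase Ckm was at -0.49 ± 0.122 (adjusted p = 0.076). Among calcium handling genes Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 0.61 along with Casq1, and the list did not pass (adjusted p = 0.316). Among 16 sarcomere genes of the adult ventricle Mybpc3 rose (0.46 ± 0.0913, adjusted p = 0.0336). That call was lost when quantile normalization was left out or arrays were scaled to the same median (changes of 0.12 and 0.20). The sarcomere list had an adjusted p of 0.536. In the extracellular matrix list of 34 genes Ccn2 and Tgfb1 rose and the basement membrane collagen Col4a1 fell (-0.98 ± 0.149), with 2 higher and 4 lower adjusted over the list alone and a list adjusted p of 0.203.

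Of the 39 named genes past the threshold in this comparison, 18 kept that call without each array in turn, and 21 lost it at least once. Pik3r1, Ppara, Myh7, Tpm2, Ccn2, Myl1, Casq1, Hrc, Akap9, Gdap10 and Col4a1 were among the former. Irs2 lost it without any array but caPI3K replicate 2 or 3 (log2 fold change 1.41 to 1.70 with 1 array left out), Akt2 without any but dnPI3K replicate 3 (0.48 to 0.68), and Tgfb1 without any but caPI3K replicate 1 or 3 or NTG replicate 3 (1.89 to 2.37). Fabp3 lost it without any dnPI3K array or NTG replicate 2 (-0.54 to -0.44), Acta2 without dnPI3K replicate 1 or 3 or NTG replicate 2 (0.90 to 1.16), and Myl4 (-7.00 to -4.51) and Myl7 (-6.61 to -4.35) without any array but caPI3K replicate 3 or NTG replicate 3. The count of probe sets fell to 82 without dnPI3K replicate 2, 95 without NTG replicate 2, 99 without dnPI3K replicate 3, 109 without dnPI3K replicate 1, 148 without NTG replicate 1 and 151 and 153 without caPI3K replicates 2 and 1. The fatty acid oxidation list did not pass without dnPI3K replicate 1 (mean -0.12), nor did the fetal and hypertrophy list without dnPI3K replicate 1 (mean 0.13) or NTG replicate 3 (mean 0.03). With the 3 arrays of highest Myl4 and Myl7 left out, which kept 1 NTG array, 27 probe sets passed, of which 17 were among the 232. Of 37 named genes 33 then lost their call, among them Casq1, Ppara (-1.85), Myh7 (1.35), Ccn2 (1.36) and Myl1 (-1.46), while Pik3r1, Tpm2, Gdap10 and Tbc1d10a kept it. With the mean Myl4 and Myl7 level as a covariate 74 passed. Both settings were chosen after seeing the data. The change of Casq1 lay at -2.03 to -1.73 over all alternatives, so it stayed about as large where its call was lost.

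**Figure D4:**
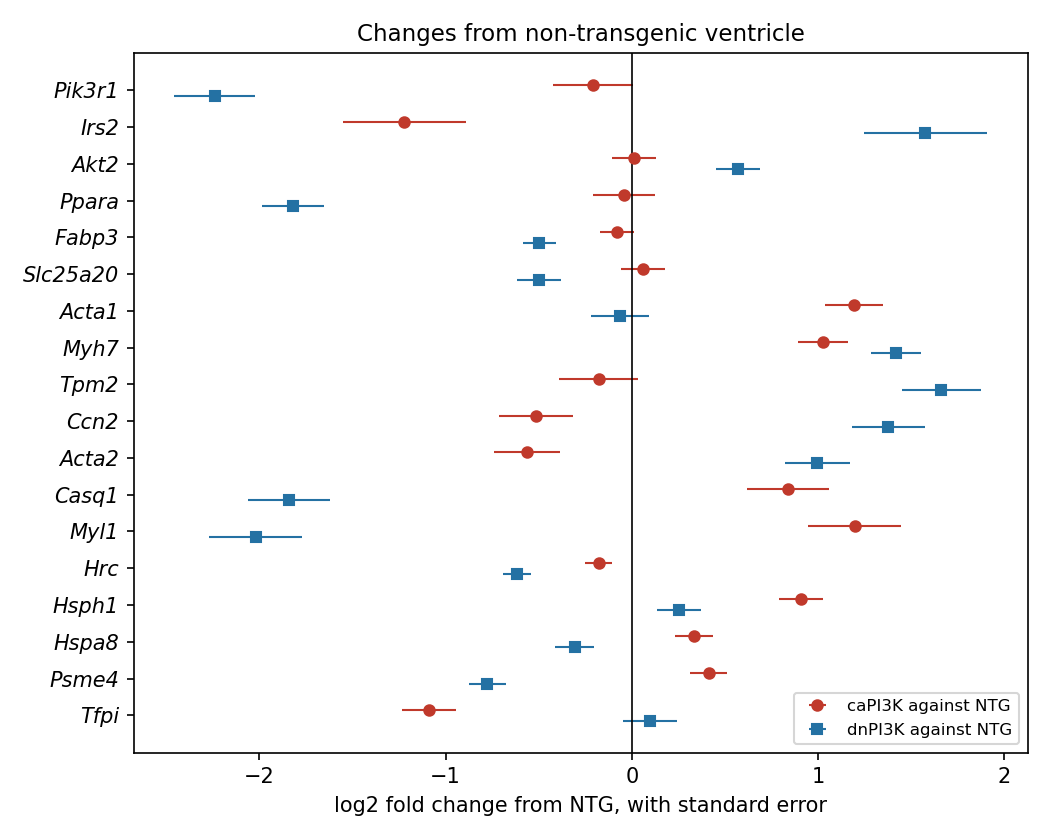
Log2 fold change from NTG, with its standard error (horizontal bars), of 18 named genes in caPI3K (circles) and dnPI3K (squares), 3 arrays per group. Pik3r1 (-2.24) and Ppara (-1.82) lie far below 0 in dnPI3K and near 0 in caPI3K, Myh7 lies above 1 in both, and Acta1 lies above 1 in caPI3K and near 0 in dnPI3K.

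The comparison of caPI3K with dnPI3K sets the larger against the smaller hearts and tests whether the effects of both transgenes against the shared controls differ. Acta1 was higher in caPI3K by 1.26 ± 0.155 on the log2 scale (adjusted p = 0.00164), Nppa was lower (-2.22 ± 0.461, adjusted p = 0.0282), and Myh7 did not differ past the threshold (-0.39 ± 0.134, adjusted p = 0.16). Pik3r1 (2.03 ± 0.216) and Ppara (1.78 ± 0.166) were higher in caPI3K. Irs2 was lower, at 61.6 ± 25.9 against 410.8 ± 74.9 (-2.80 ± 0.331, adjusted p = 0.00138), and so was Ccn2, at 1178 ± 307 against 4336 ± 910. Myl1 was 9.31-fold higher in caPI3K (10920 ± 2350 against 1164 ± 171) and Casq1 was 6.40-fold higher (4966 ± 1240 against 771.6 ± 182).

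Past the threshold were 345 probe sets, 181 higher and 164 lower in caPI3K, and 1749 had an unadjusted p under 0.05. The NTG mean lay between the transgenic groups for 272 of the 345, beyond caPI3K for 65 and beyond dnPI3K for 8. The 345 were chosen for a gap between the transgenic groups, which by itself tends to place NTG between them. The count of 272 is therefore no evidence of opposite effects. The NTG mean was nearer to caPI3K for 288, with a median position of 0.769 on a scale from dnPI3K at 0 to caPI3K at 1. Only the dnPI3K arrays stood apart in spike-in and ribosomal RNA controls and in animal series. A batch of these arrays could by itself place NTG nearer to caPI3K, so the position does not rank the effects of the transgenes. In dnPI3K against NTG 153 of the 345 also passed, and in caPI3K against NTG 8. By the brightest probe set of each gene, the other largest differences were higher in caPI3K for Akap9 (3.17), Gdap10 (2.60), Tpbpa (2.46), Egf (2.38, second probe set -0.67), Zbtb12 (2.19), Crhr2 (2.16, second probe set 0.03), Amot (2.07) and Pcdh7 (2.05, second probe set 0.33). They were lower for Tbc1d10a (-3.16, second probe set -0.43), Bex1 (-2.86), Rad51b (-2.56), Lamb3 (-2.26), Igfbp3 (-1.96), Slc16a7 (-1.94) and Tpm2 (-1.84, second probe set 0.95). The unnamed probe set was lower by 2.99, and Wnk1 was higher by 2.80 and 2.71 on a pair of probe sets that passed and at 0.31 on its brightest. Bex1 was on the floor on all 3 caPI3K arrays, and Crhr2 was on it on all 3 dnPI3K arrays, so their sizes and ranks depend on the floor. Over all alternatives Bex1 lay at -4.78 to -1.19. With the floor at the 40th percentile Crhr2 (0.78) and Slc16a7 (-0.37) did not pass, and Slc16a7 (-3.15) did not with the floor at the 5th. With the floor at the 40th percentile Akap9 (1.69), Tpbpa (1.05), Egf (1.27), Zbtb12 (0.90), Amot (1.17), Bex1 (-1.19) and Rad51b (-1.69) passed with smaller differences.

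Fatty acid oxidation genes stood higher in caPI3K than in dnPI3K (25 genes, 19 above 0, mean 0.26, adjusted p = 0.00825, and adjusted p = 0.519 with an estimated correlation). Ppara, Slc25a20 (0.56 ± 0.118), Fabp3 (0.42 ± 0.0893) and the thiolase Acaa2 (0.52 ± 0.115) were among the 5 that passed as higher, and adjusted over the list alone 7 were higher and 2 lower. Heat shock and chaperone genes stood higher as well (24 genes, mean 0.26, adjusted p = 0.00825, and adjusted p = 0.238 with an estimated correlation). Hspa8 (0.64 ± 0.104), Hsph1 (0.65 ± 0.119) and Hsp90aa1 (0.71 ± 0.135, second probe set -0.76) passed, and 10 did adjusted over the list alone. Of 42 proteasome genes Psme4 (1.19 ± 0.0998), Psmb7 (0.55 ± 0.104) and Psmb3 (0.52 ± 0.117) were higher, the same number as adjusted over the list alone (mean 0.17, adjusted p = 0.00825, and adjusted p = 0.238 with an estimated correlation). Of 34 extracellular matrix genes 28 were above 0 (mean 0.17, adjusted p = 0.0143, and adjusted p = 0.436 with an estimated correlation). Col4a1 (0.88 ± 0.149), Col8a1 (0.98 ± 0.179) and Col1a1 (0.99 ± 0.190) were higher, while Ccn2 and the metalloproteinase inhibitor Timp3 (-0.82 ± 0.151) were lower, and 7 were higher and 4 lower adjusted over the list alone.

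Vascular smooth muscle markers stood lower in caPI3K (10 genes, mean -0.42, adjusted p = 0.019, and adjusted p = 0.238 with an estimated correlation). Acta2 (-1.56 ± 0.175) and smooth muscle myosin Myh11 (-1.20 ± 0.261) passed, and 4 were lower adjusted over the list alone. Skeletal muscle markers stood higher (14 genes, mean 0.57, adjusted p = 0.0407, and adjusted p = 0.238 with an estimated correlation), with Myl1 and Casq1 as the genes that passed, in the list alone as well. In the PI3K-Akt-mTOR list Pik3r1 was higher and 4 genes were lower, among them Irs2, Akt1 (-0.90 ± 0.171, adjusted p = 0.0175) and Akt2 (-0.56 ± 0.117, adjusted p = 0.0286). Adjusted over the list alone 1 was higher and 7 lower, and the list did not pass (adjusted p = 0.0716). Of 21 fetal and hypertrophy marker genes 1 was higher and 5 were lower, 2 and 6 adjusted over the list alone, with a median of 0.05, a mean of -0.12 and a list adjusted p of 0.27. Of the PI3K subunit genes, Pik3ca (-0.63 ± 0.226), Pik3cd (-1.19 ± 0.407, second probe set -0.45) and Pik3r2 (0.48 ± 0.455) did not pass. The Nppb difference (-0.63 ± 0.146, adjusted p = 0.0428) did not pass with the deposited values or with arrays scaled to the same median, and Myh6 (-0.06) and Atp2a2 (0.00) changed sign under both.

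Of the 60 named genes past the threshold here, 26 kept the call without each array in turn, among them Acta1, Irs2, Pik3r1, Ppara, Ccn2, Tpm2, Myl1, Casq1, Acta2, Psme4 and Hspa8, and 34 lost it at least once. Nppa lost it without caPI3K replicate 1 or 2 or any dnPI3K array (-2.60 to -1.96), Akt1 without replicate 2 or 3 of either group (-0.83 at the weakest), Akt2 without any caPI3K array or dnPI3K replicate 1 or 2 (-0.67 to -0.47), and Fabp3 (0.36 to 0.48) and Myh11 (-1.41 to -0.93) without caPI3K replicate 2 or 3 or any dnPI3K array. The count was lowest without dnPI3K replicate 2 (134) and caPI3K replicate 2 (142), followed by caPI3K replicate 1 (176), dnPI3K replicate 3 (186), caPI3K replicate 3 (213) and dnPI3K replicate 1 (221). Without dnPI3K replicate 1 the fatty acid oxidation list did not pass (mean 0.14), and without caPI3K replicate 1 (mean 0.09) or dnPI3K replicate 2 (mean 0.14) the matrix list did not. The skeletal muscle list did not pass without caPI3K replicate 1 or 3, dnPI3K replicate 2 or 3, or NTG replicate 2.

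The moderated F found 280 probe sets that differed between the 3 groups. Across probe sets, which are not independent replicates, the log2 fold changes of caPI3K and dnPI3K against the shared NTG arrays had a Pearson correlation of 0.373. Unchanged groups with the same shared controls gave 0.499 on average in simulations (range 0.468 to 0.529). The covariance was 0.0596, above the simulated mean of 0.0477 (range 0.0441 to 0.0519) by 0.0119, and 61.9% of probe sets had the same sign in both, against 66.7% in simulations (65.8 to 68.0). Simulated probe sets were independent, so these ranges leave out the spread that correlated genes add. The real correlation lay between 0.434 and 0.515 without 1 NTG array and between 0.335 and 0.358 without 1 transgenic array. The number of arrays per group by itself shifts the correlation that shared controls give. The simulations had 3 arrays per group, so they give no range for these values. As the spread from correlated genes is unknown, values outside the simulated ranges decide nothing here. Of the probe sets past the threshold, 1 was higher in both transgenic groups (Myh7), and the unnamed probe set was the 1 with opposite changes. Independent lists would share 0.0507 in the former way, a value that leaves out the shared controls, so part of any excess may come from them. The 3 NTG arrays were not divided between the transgenic groups, since 1 of these would have been left with 1 control array.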

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

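The tests of explanations for the dnPI3K arrays were chosen after the differences had been seen. Control probe sets outside the comparisons stood out where the 3 arrays of a transgenic group all exceeded the NTG mean by more than 3 SD. For 18S ribosomal RNA, the 3′ control averaged 6059 (3303 to 8097) on dnPI3K arrays against 542.3 ± 112 on NTG arrays, and the middle control averaged 332.1 (218 to 557.2) against 58.5 ± 14.6. The control for the antisense strand of the Actb 5′ end averaged 170 (157.3 to 187.5) on caPI3K arrays against 127.1 ± 5.67 on NTG arrays, a difference for which no explanation was tested.

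The dnPI3K arrays differed from the others in these controls and in the first principal component. RNA degradation stays open, since the ratios point in opposite ways: their mean Gapdh 3′ to 5′ ratio differed from that of NTG by -0.0358, while their Actb ratios of 1.28 to 1.30 lay above those of 5 of the other 6 arrays, 1 NTG array being higher at 1.31. Signals of single probe sets are argued against as the whole source in caPI3K against dnPI3K. There, 119 called probe sets had another for their gene. Of these, 76.5% changed with the same sign as the brightest other one, against 56.3% of those not called (exact binomial test, one-sided p = 3.79e-06). Probe sets of 1 gene entered as separate trials, so this p is likely too small. The other probe set mostly changed less, with a median ratio of 0.324, and in 31 cases it passed with the same sign. In dnPI3K against NTG this stays open (63% against 54.9%, exact binomial test, one-sided p = 0.0698). The median ratio there was 0.164, and in 15 of 92 cases the other probe set passed with the same sign. Separate labelling or hybridisation of the dnPI3K samples stays open as a candidate explanation, because their spike-in controls read 57.5% of those on the other arrays and no other group shares their animal series, so that such a batch and the dnPI3K transgene cannot be told apart.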

How the results depend on the processing

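The settings that deal with Myl4 and Myl7 were chosen after seeing the data, and the other settings were planned. No paired analysis was possible because replicate numbers follow the order of deposition and pair no animals; the animal number series was used as a block for caPI3K against NTG. Single genes were followed with the deposited values, median scaling, both other floors, the settings for Myl4 and Myl7 and each array left out, and under these none of the named genes past the threshold changed direction. Scaling each array to the same median ended the call of 0 of 8 genes in caPI3K against NTG, 3 of 39 in dnPI3K against NTG and 10 of 60 in caPI3K against dnPI3K. With the deposited values these numbers were 1, 3 and 4, with the floor at the 5th percentile 2, 3 and 2, and with the floor at the 40th percentile 1, 6 and 2. Leaving out the 3 arrays of highest Myl4 and Myl7 ended 8 of 8, 33 of 37 and 17 of 60 calls, and their level as a covariate 8 of 8, 15 of 37 and 13 of 60. The former setting keeps 1 NTG array. Over all alternatives run for single genes, the log2 fold change in caPI3K against NTG lay at 1.13 to 1.36 for Acta1, 0.834 to 0.985 for Hsph1 and -1.98 to -1.56 for Sprr2g, whose calls ended under both.

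For caPI3K against NTG, dnPI3K against NTG, caPI3K against dnPI3K and any difference between the 3 groups, the numbers of probe sets past the threshold were 9, 232, 345 and 280. With no filter on dim probe sets they were 1, 138, 219 and 166. With no intensity trend they were 1, 94, 151 and 122, although the probe sets tested were the same. Leaving out 1 array in turn gave 0 to 20, 82 to 235, 134 to 435 and 116 to 377. Array weights raised the count for caPI3K against dnPI3K to 527. A fit of only the 2 groups compared gave 0 and 94 for caPI3K and dnPI3K against NTG, and the animal series as a block gave 0 for the former. Settings with 0 calls in limma had 565 to 837 probe sets with an unadjusted p under 0.05, where a share of 0.05 is expected with no change. With the 3 arrays of highest Myl4 and Myl7 left out, the counts were 1, 27, 270 and 181, and fewer arrays entered the fit. Of these, 0, 17 and 210 were among the probe sets called with all arrays in the respective comparison. With the mean Myl4 and Myl7 level as a covariate they were 1, 74, 263 and 163. Apart from the fits with fewer arrays, the cause was not tested.

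The correlation between both effects against the shared controls, 0.373 with all arrays, was 0.417 with the floor at the 5th percentile, 0.286 with the floor at the 40th, 0.278 for probe sets above the median, 0.39 with array weights, 0.36 with 1 probe set per gene and 0.335 to 0.515 with 1 array left out. It was 0.594 with the high Myl4 and Myl7 arrays left out and 0.478 with the covariate. Leaving out arrays by itself shifts the correlation that shared controls give, since the number of arrays per group changes. Other causes were not tested.

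With an estimated correlation between genes, 0 lists passed in each comparison, and 4, 2 and 5 had an unadjusted p under 0.05 in camera. With the deposited values, 2 lists passed in caPI3K against NTG and 5 in dnPI3K against NTG. Leaving out 1 array gave 1 to 6 lists, 1 to 5 and 4 to 7, and leaving out the high Myl4 and Myl7 arrays gave 0 in caPI3K against NTG; the cause was not tested for the deposited values.

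The changes that took the opposite sign were not past the threshold. In caPI3K against NTG, Nppa was at 0.0141 with the high Myl4 and Myl7 arrays left out, Nppb at 0.0148 and Atp2a2 at 0.002 with arrays scaled to the same median, and Nppb ranged from -0.195 to 0.091 with 1 array left out. In dnPI3K against NTG, Pik3r2 was at -0.0534 with the deposited values, -0.0318 with the floor at the 40th percentile, -0.225 with the high arrays left out, -0.185 with the covariate and -0.337 to 0.33 with 1 array left out. Pik3cd was at -0.276 with the high arrays left out, -0.519 with the covariate and -0.158 to 0.394 with 1 array left out, and Acta1 at 0.0535 with the high arrays left out and -0.233 to 0.0761 with 1 array left out. In caPI3K against dnPI3K, Myh6 and Atp2a2 were at 0.345 and 0.283 with the deposited values and at 0.349 and 0.287 with arrays scaled to the same median, and Atp2a2 at -0.0889 to 0.0792 with 1 array left out; the cause was not tested.

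Signal over background limits the dim probe sets. Of 12422 probe sets other than array controls, 10645 lay above the floor on at least 3 arrays. Fold changes of genes with a group on the floor, such as Bex1, Crhr2, Akap9, Aff1 and Eepd1, depend on that floor. With the floor at the 40th percentile Eepd1, Tgfb1, Aff1, Sema3b, Myl4, Myl7, Crhr2 and Slc16a7 lost a call, and with the floor at the 5th Eepd1, Tpbpa, Aff1, Myl7, Slc16a7, Eef1d and Mfap5 did.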

Other observations

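The tests of explanations for Myl4 and Myl7, Nppa and Myh7 were chosen after these results had been seen, as were the genes Stard10, Dkk3 and Scd1. Among gene lists that did not pass, the circadian list of 14 genes held changes in dnPI3K. The clock genes Per3 (1.17 ± 0.208, adjusted p = 0.0185) and Cry1 (0.99 ± 0.185, adjusted p = 0.024) rose against NTG, with a list adjusted p of 0.203. In caPI3K against dnPI3K, Per3 (-1.26 ± 0.208) and the nuclear receptor Rora (-1.54 ± 0.328) were lower. Of 15 angiogenic genes, Nrp1 (-0.66 ± 0.0936, second probe set 0.19), Pdgfa (-0.83 ± 0.130) and Vegfb (-0.68 ± 0.111) were lower in caPI3K than in dnPI3K, with a list adjusted p of 0.0894. For each of these genes the arrays of either group all lay beyond those of the other. That held for all 232 and all 345 probe sets past the threshold in these comparisons, so it adds nothing to the calls. In dnPI3K against NTG, Per3 lost its call without dnPI3K replicate 1 or 2 or NTG replicate 1 or 2 (0.95 to 1.37 with 1 array left out) and Cry1 without any dnPI3K array or NTG replicate 1 (0.83 to 1.13). Rora lost its call without any array but those of NTG (-1.72 to -1.21).

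The endothelial, fibroblast and interferon response lists did not pass in dnPI3K against NTG. Of 15 endothelial genes 13 were above 0 (adjusted p = 0.178), and of 24 interferon response genes 18 were above 0 (adjusted p = 0.178), with 0 genes past the threshold in limma in either list. Of 19 fibroblast genes the collagen receptor Ddr2 fell (-1.06 ± 0.166, adjusted p = 0.00947), with a list adjusted p of 0.364. Clu, a secreted chaperone on the atrial marker list, fell (-0.73 ± 0.137, adjusted p = 0.0242). Xist, which female cells express, was read on all 9 arrays, and fell in dnPI3K (-0.69 ± 0.142, adjusted p = 0.0377). Clu lost its call without any dnPI3K array or NTG replicate 1 or 2 (-0.91 to -0.62 with 1 array left out) and Xist without any array but caPI3K replicate 2 or dnPI3K replicate 1 (-0.79 to -0.60). Xist averaged 750 ± 101 in dnPI3K, 1206 ± 154 in NTG and 1199 ± 140 in caPI3K.

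Myl4 and Myl7 differed between arrays of a group, with a mean of both genes of 7074, 4186 and 269 on the NTG arrays, 575.7, 473.3 and 4941 on the caPI3K arrays and 32.2, 96.0 and 39.2 on the dnPI3K arrays. Within groups, 4 of 7482 other genes followed them past the threshold, and 3 of these were among the 11 other atrial markers tested (Nppa, Dkk3 and Stard10, the remaining gene being Scd1; exact hypergeometric test, one-sided p = 9.45e-09). Atrial tissue in some caPI3K and NTG samples is a candidate explanation for the spread of these genes, although the labels name only the ventricle. Nppa in caPI3K against dnPI3K stood at -2.22 with all arrays (limma adjusted p 0.00538 to 0.119 with 1 array left out). It stood at -2.58 with the 3 arrays of highest Myl4 and Myl7 left out. Within groups Nppa rose with Myl4 and Myl7, by 0.297 on the log2 scale per 1000 intensity units. Atrial tissue would thus raise Nppa in caPI3K, and leaving out its high array was bound to widen the gap. That setting is therefore no test of atrial tissue as a source of the Nppa difference. The direction still argues against atrial tissue in the caPI3K samples as that source. Mean Myl4 and Myl7 levels were higher on caPI3K arrays (473.3 to 4941) than on dnPI3K arrays (32.2 to 96.0), while Nppa was lower. Myl4 and Myl7 were also lower in dnPI3K than in NTG past the threshold, and whether that comes from the tissue taken or from the genotype cannot be told apart.

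Myh7 was higher in both transgenic groups than in NTG. Binding of Myh6 transcript to the Myh7 probe set stays open, since Myh6 changed by -0.116 in caPI3K while its probe set was among the brightest, which limits what that value can show. A transgene transcript that holds Myh7 sequence may add signal in both groups, if the transgenes were built with myosin heavy chain gene sequence, which the labels do not say. The other Myh7 probe set changed by 0.661 ± 0.436 in caPI3K, which is too imprecise to decide. In dnPI3K that probe set rose by 2 ± 0.436 (limma adjusted p = 0.0443), so the rise there was not confined to a single probe set. Both probe sets are of a type that shares sequence within a gene family. The second therefore does not exclude signal from Myh6 either. Whether a transgene would hold the sequence read by both probe sets is not known, so a transgene transcript stays open in dnPI3K as well. Re-expression of Myh7 in both genotypes also stays open.

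The splits of the arrays into other groups were planned. The 6 arrays of a comparison make 10 splits, and 10 splits are too few for a share under 0.05. For caPI3K against NTG the real split gave 9 probe sets and the highest other 3, and for lists 5 and 5, so that 2 splits gave as many lists. For dnPI3K against NTG the numbers were 232 and 0 probe sets in limma, and 3 and 4 lists, with 4 splits that gave as many lists. For caPI3K against dnPI3K they were 345 and 0 probe sets, and 6 and 2 lists. In each comparison 1 split, the real one, gave as many probe sets, and this held for lists in caPI3K against dnPI3K. For any difference between the 3 groups, 100 of the 280 possible splits were drawn. Of these 1, the real one with 280 probe sets, gave as many, and the highest other gave 190. A share of 1 in 100 makes a random grouping of the arrays an unlikely source of that count. It does not tell the genotypes from a batch of the dnPI3K arrays.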
